A study of Homo sapiens with 4 samples.

How the data were processed

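Hepatocyte nuclear factor 1 (HNF1) is a homeodomain transcription factor known for its role in epithelia of the liver, kidney and gut. Its binding was profiled by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in cultured epithelial cells from the caput, the head region of the adult human epididymis, the duct in which sperm mature. The 4 libraries were 2 HNF1 ChIP libraries and 2 input libraries made without antibody, 1 of each per culture. Per the labels' protocols, nuclei were isolated and sonicated, the complexes were precipitated with an antibody named only as against HNF1, and libraries were size-selected and amplified by PCR before sequencing on an Illumina HiSeq. Culture and ChIP details that belong to single donors were left out.

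The analysis started from 1 table, a deposited list of 10480 peaks that combines both ChIP libraries. Bowtie, HOMER and bedtools and the genome build hg19 are named in the submitters' processing notes. Their versions, their order, the way the replicates were combined and the use of the inputs are not given in the sources used here. Each peak has a chromosome, a start, an end, a name and a whole-number score, and the authors listed the peaks in descending order of that deposited score. What the score counts or is normalized to is not given in the sources used here, so scores were used within the list only, mainly to rank and filter peaks. Sums and means of scores describe the scores as deposited, and 2 tests of the closing section, on chromosome X and on the score steps, assume that scores follow read numbers. Every peak is 133 bp wide, so width carries no information. The list has no value for a single library and no read totals. Sequencing depth is therefore unknown, no ChIP library could be compared with its input or with the other replicate, and no interval in the text covers the spread between cultures. All p-values describe the positions, scores or names of peaks in this 1 combined list, and peaks and chromosomes are not replicates.

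The 18 peaks on chromosome Y were left out, which left 10462 peaks on the 22 autosomes and chromosome X. Positions are printed 1-based in hg19. The list was tested in 2 ways fixed before the data were examined. First, the count of each chromosome was compared with its share of the summed span, from the first to the last listed peak of each chromosome, with an exact two-sided binomial test and Benjamini-Hochberg adjustment over 23 chromosomes. Densities have exact Poisson 95% intervals, which cover counting error only. Second, the number of peaks with another peak within 10 kb, midpoint to midpoint, was compared with 1000 random placements of the peaks along the span of their chromosomes, a two-sided permutation test. Windows of 1 Mb were compared with the mean of their own chromosome by an exact one-sided Poisson test, adjusted over 2929 windows. This last test was added after the data were seen. Comparisons of scores between sets of peaks used 100000 resamples.

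On simulated peak sets of the same size, the neighbour test called 1 of 20 unclustered sets and 20 of 20 sets in which 10% of the peaks had been planted beside another. The chromosome test called 80 of 80 simulated shifts to 0.7 or 1.3 times the expected density in the right direction. Across 20 sets with no shift it called 3 chromosomes. Apart from the planted neighbours, the simulated peaks were independent and even in density along a chromosome. The listed peaks varied more than that, so these rates of calls need not hold for them.

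The alternatives fixed before the data were examined and run were the peaks at or above the median score for the list and the chromosomes, merging of nearby peaks and other neighbour distances. Added after the data were seen were the peaks at or above the median score for the neighbours, random shifts of each peak, spans without the longest stretch between peaks, autosomes alone, chains of peaks counted once, a wider spread taken from 10 Mb windows, and a count taken from the peak names. Some planned results were not made, because a genome sequence and gene annotation of hg19 were not used here and coordinates were not converted between builds. These were the classes of peaks around genes, the HNF1 motif with 33 motifs of other factors, and the overlap with 15 gene lists and 18 gene families. The rule for named genes was to take the genes nearest the 15 peaks of highest score and the genes with the most peaks. It was applied to the regions themselves, giving the 15 peaks of highest score, and, chosen after the data were seen, the windows with 15 or more peaks. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.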

Results

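HNF1 ChIP-seq in cultured caput epididymis epithelial cells gave 1 combined list of peaks from 2 ChIP libraries, each with an input library from the same culture. The list shows where in the genome peaks were called with the antibody against HNF1, not checked here by the HNF1 motif. It holds no value per library, so read depth is unknown, ChIP and input could not be compared, and the spread between the 2 cultures could not be measured. Each p-value refers to peaks within this list, not to libraries. The regions are given by position, and the genes at them were not analysed here.

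The 10462 peaks on the autosomes and chromosome X spread over every one of these 23 chromosomes, with 3.60 peaks per Mb of span and a median distance of 124 kb between neighbouring peaks. Scores were strongly skewed. The median score was 10, the quartiles were 7 and 16, and 53.8% of the peaks scored 10 or less. A score of 50 or more was reached by 107 peaks and a score of 100 or more by 15 peaks. These 15 peaks, 0.143% of the list, held 1.87% of the summed score. The score is the authors' own value for a peak.

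**Figure D1:**
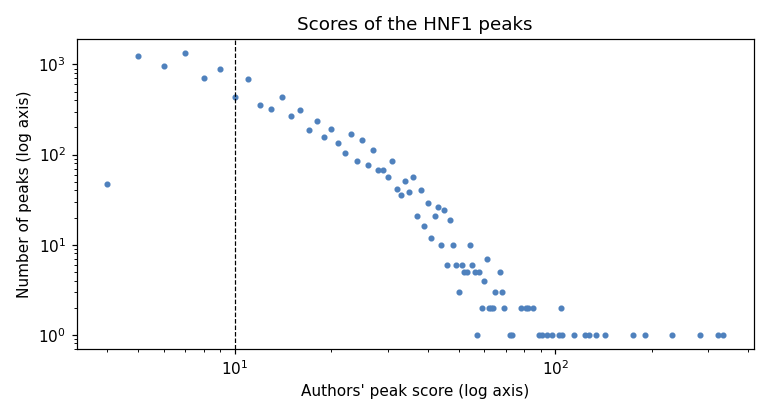
Number of HNF1 peaks at each value of the authors' peak score, both axes logarithmic, over the 10462 peaks of the autosomes and chromosome X. The dashed line marks the median score of 10, and 15 peaks lie at 100 or more.

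Among the peaks in the combined list, the highest score was on chromosome 1 from 156186269 to 156186401 (hg19), at 333. Its name carries the number 2, so the ranking covers only the peaks left in the list. The next was on chromosome 17 from 33478108 to 33478240, with a score of 322. The third, on chromosome 20 from 26190022 to 26190154, scored 283, and another of the 15 lay only 1035 bp from it, from 26188987 to 26189119, with a score of 175. Chromosome 16 carried a peak of score 231 from 33963257 to 33963389, the nearest other listed peak being 2250900 bp away. Chromosome X carried a peak of score 191 from 108297674 to 108297806. The other peak of the 15 on chromosome 1, from 234953221 to 234953353, scored 143. The peak on chromosome 9 from 79186760 to 79186892 scored 134, that on chromosome 8 from 2274959 to 2275091 scored 127, and that on chromosome 4 from 70296638 to 70296770 scored 124. Chromosome 2 held 3 of the 15. They lay from 34852152 to 34852284 with a score of 114, from 67799357 to 67799489 with a score of 105, and from 43421428 to 43421560 with a score of 103. The other two, each with a score of 104, lay on chromosome 12 from 127650451 to 127650583 and on chromosome 17 from 31149765 to 31149897. The 15 peaks fell on 10 chromosomes. What the score counts is not given and the inputs could not be compared. Whether any of the 15 peaks lies in repeated sequence was also not checked. A high score alone therefore does not show strong HNF1 binding.

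HNF1 peaks were sparse on chromosomes X and 19 and, among the listed peaks, on chromosome 16. Chromosome X had 218 peaks where its span predicted 544, a density of 1.44 per Mb (95% interval 1.26 to 1.65) against 3.72 (3.65 to 3.79) on the autosomes. Chromosome 19, known as the most gene-dense human chromosome, had 108 peaks against 206 expected, or 1.89 per Mb (1.55 to 2.28). Chromosome 16 had 220 against 321 expected, or 2.47 per Mb (2.15 to 2.81). Density was above expectation on chromosome 6, with 757 peaks against 612 and 4.45 per Mb (4.14 to 4.78), and on chromosome 3, with 826 against 710 and 4.19 per Mb (3.91 to 4.49). Chromosomes 2 and 15 lay above expectation by smaller factors, 1.10 and 1.15.

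By the exact binomial test these 7 of 23 chromosomes passed an adjusted threshold of 0.05, 4 above and 3 below their share. The adjusted p was 8.0e-58 for chromosome X, 7.5e-13 for 19, 1.3e-08 for 16, 2.7e-08 for 6, 4.2e-05 for 3, 0.0091 for 2 and 0.044 for 15. The binomial test takes peaks as independent. Counts in 10 Mb windows, empty windows included, varied 5.00 times as much as independent peaks of even density would. Stretches to which reads cannot be mapped may be part of this factor. With the spread widened by it, only chromosomes X and 19 passed, at adjusted p of 3.0e-09 and 0.024. Chromosomes 6 and 16 then had adjusted p of 0.052 and 0.059, and chromosomes 3, 2 and 15 had 0.20, 0.64 and 0.86. The names of the peaks carry numbers. Of the numbers up to the highest on each chromosome, 49.7% were absent on 16, 36.5% on 19 and 26.1% on X. On chromosomes 21, 10 and 20, which did not pass the binomial test, 63.8%, 38.3% and 36.4% were absent. A high absent share thus did not always go with a low density. Chromosome X peaks also had lower scores, with a median of 8 against 10 on the autosomes. A peak on X scored higher than an autosomal peak with a probability of 0.404, tied scores being split evenly. The permutation p was 1e-05, the smallest that 100000 resamples can give.

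**Figure D2:**
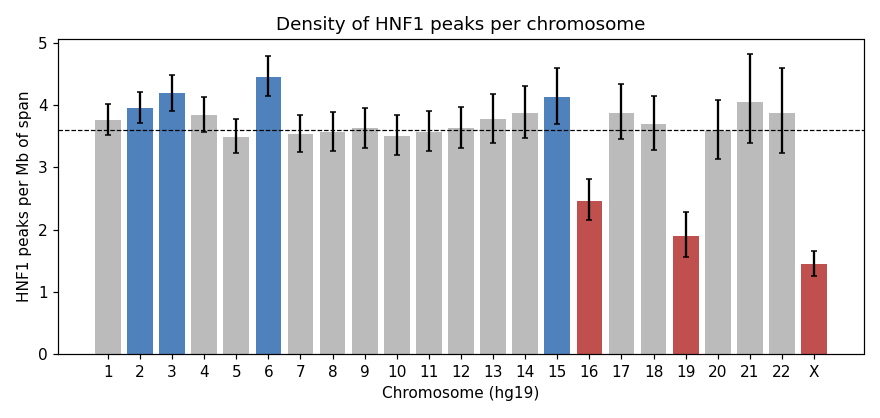
Density of HNF1 peaks in peaks per Mb of span (first to last listed peak) for each chromosome of hg19, with exact Poisson 95% intervals as error bars and the mean of all chromosomes, 3.60, as a dashed line. Blue and red bars mark the 4 chromosomes above and the 3 below their share by the binomial test, and grey bars the rest; X and 19 are lowest at 1.44 and 1.89.

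HNF1 peaks lay close to one another far more often than randomly placed peaks. Of the 10462 peaks, 2168 (20.7%) had another peak within 10 kb, against a mean of 749 (7.16%) in 1000 random placements, a ratio of 2.89. No placement exceeded 877, and the permutation p was 0.002, the smallest that 1000 placements can give. Within 2 kb the shares were 6.89% and 1.48%, a ratio of 4.67, and within 50 kb 50.4% and 30.9%, a ratio of 1.63. The closest peaks were 293 bp apart, and 202 pairs of neighbouring peaks lay within 1000 bp of each other. Each peak was instead shifted at random by up to 500 kb, which keeps regional density only in smoothed form. The ratio was then 2.16, and with shifts of up to 100 kb it was 1.67.

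**Figure D3:**
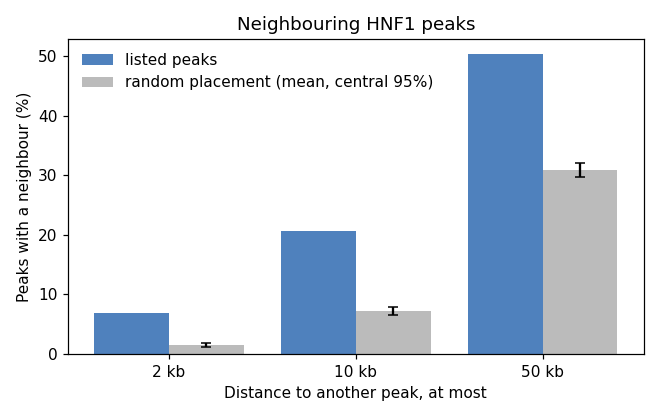
Percent of HNF1 peaks with another peak within 2, 10 or 50 kb (midpoint to midpoint) in the list (blue) and in 1000 random placements along the same chromosomes (grey, mean with the central 95% as error bars). The listed share within 10 kb is 20.7% against 7.16%.

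Chains of peaks joined by steps of at most 10 kb were mostly short. There were 868 chains of 2 peaks, 126 of 3, 11 of 4 and 2 of 5, while 8294 peaks stood alone. One chain of 5 lay on chromosome 3 from 101891844 to 101901355, 9.51 kb long, with scores from 7 to 26. The other lay on chromosome 17 from 55434859 to 55454764, 19.9 kb long, with scores from 8 to 20.

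On the scale of 1 Mb, 50 of 2929 windows held more peaks than the mean of their chromosome at an adjusted Poisson p under 0.05, and these held 654 peaks, or 6.25% of the list. The Poisson test takes peaks as independent, whereas window counts varied 2.51 times as much as independent peaks would, so this count and the p-values of single windows overstate the evidence. No peak was found in 426 windows, against 113 expected with an even density. Windows without a peak include stretches of the genome, such as centromeres, to which reads cannot be mapped. The densest window was on chromosome 6 from 12000001 to 13000000, with 18 peaks against 4.45 expected (exact Poisson test, adjusted p = 0.0011) and a top score of 48. The window on chromosome 6 from 25000001 to 26000000 held 16 peaks with a median score of 7, the lowest median of the 12 windows with 15 or more peaks, and that from 111000001 to 112000000 held 15.

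A further 5 windows held 16 peaks each. On chromosome 7 from 47000001 to 48000000 and on chromosome 22 from 29000001 to 30000000 the median score was 14, with top scores of 59 and 62. On chromosome 2 from 43000001 to 44000000 the top score was 103, from the peak at 43421428 to 43421560, and the median was 12. On chromosome 5 from 142000001 to 143000000 no peak scored above 25, and on chromosome 3 from 101000001 to 102000000, which holds the chain of 5 peaks described above, none scored above 26. Windows with 15 peaks also lay on chromosome 8 from 8000001 to 9000000, chromosome 15 from 63000001 to 64000000, chromosome 18 from 3000001 to 4000000 and chromosome 20 from 11000001 to 12000000. Across the 12 windows the adjusted p lay between 0.0011 and 0.013.

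**Figure D4:**
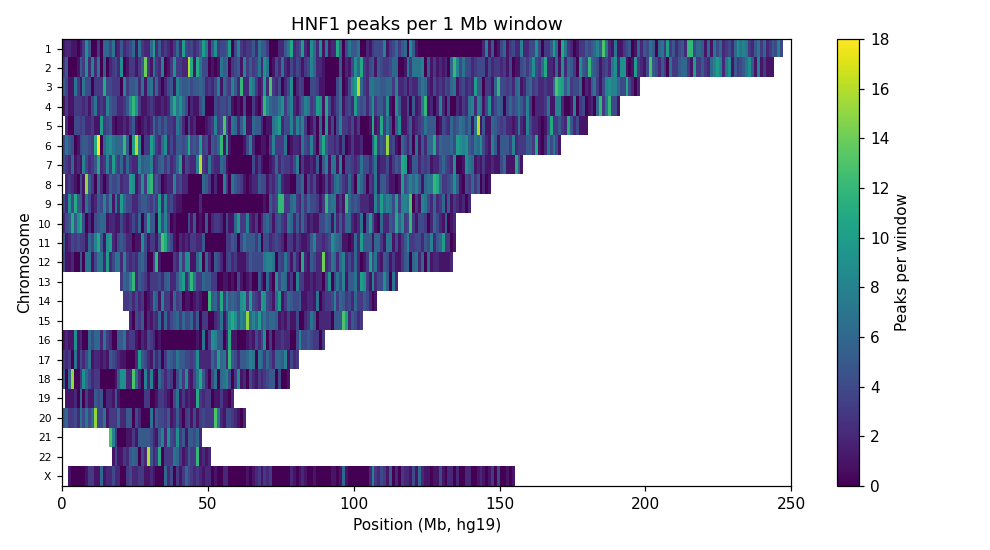
HNF1 peaks per 1 Mb window along each chromosome (hg19, position in Mb; colour gives the number of peaks, white lies outside the span of the listed peaks). The brightest window is on chromosome 6 with 18 peaks, and the rows of chromosomes 19 and X hold the lowest densities, 1.89 and 1.44 peaks per Mb.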

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

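All tests of the peak names were chosen after the values were seen. Each peak's name ends in a number that occurs once on its chromosome. Over all peaks of a chromosome it follows the score closely, with Spearman's rho between -0.99 and -0.97 on the 23 chromosomes. The order did not hold throughout the first 20 numbers. On chromosome 9 number 1 scored 53 and number 5 scored 134, and on chromosome 4 number 1 scored 82 and number 19 scored 124. The comparisons of the listed peaks did not use these names. If the numbers start at 1, which is inferred, 4149 of the 14611 up to each chromosome's highest (28.4%) are absent from the combined list. A candidate source is a longer list of peaks from which some were dropped. Dropping of weak peaks would go with the rise of the absent share to 35.9% for the numbers above 400 and up to 800 and 50.03% (861 of 1721) beyond. As the whole cause it is argued against only if the numbers 1 to 20 stood for stronger peaks than 21 to 100. Of the numbers 1 to 20, 22.8% were absent (105 of 460) against 12.2% of the numbers 21 to 100 (permutation of signs over 23 chromosomes, p = 0.017). This difference rests on 4 chromosomes. On the other 19 the shares were 12.9% and 9.41%, and no test applies to them, since they were set apart by this outcome. Loss at 1 rate for all chromosomes is argued against too. The number absent among 1 to 20 varied between chromosomes with a variance of 26.3 against 3.53 in permutations (p = 1e-05, the smallest possible), and chromosomes 16, 10, 2 and 18 had 18, 14, 12 and 12 of 20 absent, 56 of the 105.

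The absent numbers bear on the low density of chromosome 16. Counted up to the highest number, chromosome 16 had 0.97 times its share (adjusted exact binomial p = 0.72), against 0.68 for the listed peaks. Its deficit may thus come from the dropping of peaks. The same count put chromosome 21, at 1.13 times its share for the listed peaks, at 2.23 times. Whether the absent numbers stood for binding sites is not known, so a true deficit on chromosome 16 is not excluded. Chromosome 19 stayed at 0.59 times its share (adjusted exact binomial p = 4.8e-13). Chromosomes 3 and 15, at 1.16 and 1.15 times their share for the listed peaks, had 1.05 and 1.03 times by this count (adjusted exact binomial p = 0.17 and 0.63). Removal of peaks in repeated or high-signal regions, disagreement between the replicates and true differences between the cultures remain open, and no biological explanation was tested.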

How the results depend on the processing

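The excess of neighbouring peaks kept its direction and passed the permutation test in each of the 6 alternatives, with ratios from 1.63 (within 50 kb) to 4.67 (within 2 kb). The 3 that shifted peaks by up to 500 kb (2.16) or 100 kb (1.67) or kept the peaks at or above the median score (3.28) were added after the data were seen. Restricting the list to scores at or above the median of 10 left 5270 peaks by construction, and the same 7 chromosomes passed with them. Merging overlapping peaks changed nothing, since none overlap, and merging within 1000 bp left 10260. Of the alternatives to the chromosome test, all but the median score were added after the data were seen. Autosomes alone gave 4 chromosomes (3 and 6 above, 16 and 19 below), in part because removing X raises the expected count of the others. The spread widened by the variance of 10 Mb windows gave 2 (19 and X). Without the longest stretch between peaks, chromosomes 1 and 9 passed in place of 2 and 15. Counting by the highest number in the peak names gave 8 (2, 4, 6, 10 and 21 above, 5, 19 and X below), with 21 at 2.23 times its share. By that count chromosomes 3, 15 and 16 no longer passed. Of the 7 called chromosomes, only X and 19 passed in every alternative run on them, and no direction was reversed. No paired analysis was possible because the list combines the replicates; leaving out a replicate could not be run for the same reason. The alternatives fixed in advance for motifs, peak classes and gene lists were not run, as no hg19 sequence or annotation was used here. Read depth is unknown, so whether weaker sites were missed cannot be judged.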

Other observations

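Merging within 1000 bp was fixed before the data were examined, and the other tests in this part were added after. The tests of the score steps, with widened intervals, at X scores of 5, 7 and 15 and with shifts of up to 100 kb also had no criterion set before their results were seen. Peaks with a neighbour within 10 kb had scores only slightly above those without. The median score was 10 against 9, and the mean was 13.7 ± 11.9 (SD over 2168 peaks) against 13.2 ± 11.6 (8294 peaks). A peak with a neighbour had the higher score with a probability of 0.518, with tied scores split evenly between the 2 sides (permutation p = 0.011). Within the 868 isolated pairs of peaks, the scores of the 2 peaks were not shown to be related, with a Spearman's rho of 0.062 and a permutation p of 0.070 across pairs.

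Chromosome X held 0.40 times its share of peaks. As the epididymis is a male organ, a candidate explanation is that a single copy of X gives each site fewer reads. If this were the whole cause and score followed reads, X peaks of score 10 or more would be as dense as autosomal peaks of score 20 or more. The ratio was 0.765, with an exact 95% interval of 0.602 to 0.960, which excludes 1 and by the criterion fixed in advance would rule this out. That interval takes peaks as independent, whereas counts in 10 Mb windows varied 1.74 times (X) and 1.76 times (autosomes) as much as independent peaks would. With that spread, added after the first interval was seen, the interval was 0.568 to 1.03. At X scores of 5, 7 and 15, against autosomal scores of 10, 14 and 30, the ratio was 0.762 (widened interval 0.602 to 0.963), 0.858 (0.668 to 1.10) and 0.618 (0.410 to 0.930), so a single copy as the whole cause stays open, since the intervals exclude 1 at some scores and not at others. At equal scores of 10 or more the ratio was 0.274.

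Neighbouring peaks were 2.89 times as frequent as in random placements. Regional density, such as gaps in mapping or regions poor in genes, is argued against as the whole cause on the scale of 1 Mb. Shifts of each peak by up to 500 kb left a ratio of 2.16 and shifts of up to 100 kb one of 1.67. Part of the excess thus goes with density on these scales. The shifts smooth density and can move peaks into gaps, so these ratios may overstate the excess that is left. The splitting of 1 site into adjacent peaks is also argued against as the whole cause, since the ratio was 2.496 after peaks within 1000 bp were merged. Merged peaks were compared only with random placement along the span, so splitting and regional density together were not tested. Grouping of HNF1 sites around particular genes stays open as a hypothesis and was not tested, as genes were not assigned.

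The number of peaks rose and fell from 1 score to the next at low scores, with 1234 peaks at a score of 5, 972 at 6, 1342 at 7, 712 at 8, 885 at 9, 436 at 10 and 698 at 11, but it fell at both following scores, to 355 at 12 and 321 at 13. A hypothesis, formed after these steps were seen, was that scores are whole read numbers multiplied by 1 factor and rounded down. The held-out prediction was not met, but the test could not decide the hypothesis. A factor of 0.412 fitted on scores 5 to 17 lowered the deviance there from 385 to 24.5, but its steps were not shown to predict those of scores 18 to 31 (Pearson's r = 0.213 over 14 scores, one-sided permutation p = 0.21). A small error in the fitted factor moves the predicted steps more at higher scores, so scaled read numbers are not excluded. With so few scores a weak relation is not excluded either, and other rounding rules were not tried.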
